A study of Mus musculus with 15 samples.

How the data were processed

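Expression had been measured on Affymetrix mouse arrays in 5 kinds of cells with 3 samples each, 15 arrays in all. The deposited intensity values (MAS5 signals from the Affymetrix Expression Console, per the submitters' processing notes, which give no versions) were used, and no raw scans were read. Per the labels, mouse embryonic fibroblasts (MEF), the embryonic stem (ES) cell line CL11 and the induced pluripotent stem (iPS) cell lines IP14D-1 and IP20D-3 share the B6D2F1 background, and IP14D-101 has the C57x129S2 background, so background and line could not be separated for IP14D-101. ES and iPS cells had grown on mitomycin C-treated feeder fibroblasts with LIF in medium holding serum or a serum replacement, and the labels do not say which medium each line had. The design text calls the samples of a group biological replicates, and the p values therefore measure the spread between these samples only.

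Each array held 45101 probe sets, of which 64 were array controls. No value was missing or below 0, no pair of arrays had identical values, and the highest Pearson correlation between arrays was 0.954. The 2% trimmed means of the arrays ran from 11141.8 to 20355.5, a ratio of 1.83, which was beyond the 5% tolerance set before the data were examined, so each array was scaled to their mean. Values were then taken as log2(signal + 16). Of the 45037 other probe sets, 34945 named a single gene, 932 named several genes and were left out, and 9160 named none. Symbols were taken from the probe annotation, and 18031 genes had an identifier in the RefSeq gene table, with 0 symbols changed. Each gene was represented by its probe set with the highest mean, which left 18193 genes.

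Background was taken as the 95th percentile of 39 olfactory receptor genes, a log2 signal of 11.04 or a signal of 2087, and 63.9% of gene values lay above it. Where the mean of the dimmer group lay below background, the change is given as at least the fold between the brighter group and the dimmer one with its arrays below background raised to it. This rule was widened after the values were seen, from groups with all arrays below background. No fold is given where both groups lay below it.

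Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each group was fitted to all 15 arrays, 10 contrasts were taken, and variances were moderated with a trend on mean expression (median prior degrees of freedom 7.60). The p values were adjusted by Benjamini and Hochberg over 18193 genes within each comparison, and an adjusted p under 0.05 counted as changed. Errors given with log2 changes are standard errors from this model, and errors given with group levels are standard deviations over 3 arrays. Genes with no overlap between the arrays of a pair of groups were counted beside the 10% of orderings in which 3 and 3 values separate by chance. Each comparison was also repeated for the 10 ways of dividing its 6 arrays into 3 and 3, which are too few for a share under 0.05.

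A total of 30 gene lists, fixed from general knowledge before the values were read, was tested with camera at a preset correlation of 0.01 and again with the correlation estimated for each list, adjusted over the lists within each comparison. They covered the pluripotency network, reprogramming factors, fibroblast and feeder extracellular matrix, mesenchymal transcription factors, epithelial junctions, the Dlk1-Dio3 cluster, other imprinted genes, sex-linked genes, 2-cell-like genes, primed epiblast, endoderm, mesoderm and primitive streak, neural ectoderm, trophoblast, germ line, chromatin and DNA methylation enzymes, proliferation, p53 and senescence, interferon response and class I MHC, cholesterol synthesis, amino acid and endoplasmic reticulum (ER) stress, hypoxia and glycolysis, oxidative phosphorylation, immediate early and serum response, LIF and STAT3 targets, HOX genes, macrophage and blood, muscle with cartilage and endothelium, ribosomal proteins, and reference genes. Members were also counted with p values adjusted over the list alone.

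Genes are named by a fixed rule. In each comparison these are the 5 largest rises and the 5 largest falls among changed genes with no overlap between arrays and a brighter mean above background, with predicted genes passed over, which left out 1 gene in each of 4 comparisons. The rule ranks by the fitted log2 change, so where a group lay below background the rank is not a measured order. For the lists described, up to 4 changed members with the largest changes are eligible. Pou5f1, Sox2, Klf4, Myc, Nanog, Col1a1, Cdh1, Meg3, Rian, Dlk1 and Xist are always eligible. Lists are described where the preset camera test or a large share of members passed, and the pluripotency, fibroblast, epithelial and Dlk1-Dio3 lists always.

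Similarity between groups was measured as the root mean square log2 difference over all genes, corrected for the spread between replicates, and as Pearson correlation between arrays. A position on the MEF to CL11 axis was calculated for each iPS array (MEF at 0, CL11 at 1), where an unchanged ES line measured on other arrays was calculated to lie at 0.951. MEF-high (1585) and ES-high (1621) genes were those differing at least 4-fold between CL11 and MEF. Genes changed against CL11 in all 3 iPS lines share the CL11 arrays, so their count is given with the count for independent lists and with the count in 20 simulations. In these the called differences of each line were dealt at random to other genes of like level, so that only chance and the CL11 values were shared. It was chosen after the counts were seen, replacing one without line differences that called no shared gene. The smallest 2-sided exact p for 3 against 3 values is 0.1.

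Results were repeated with a pseudocount of 1 or 64, quantile normalization, median scaling, all probe sets, leaving out probe sets that cross-hybridise by name, leaving out dim genes, no variance trend, fitting only the groups compared, a replicate block, leaving out each array, estimated list correlations, a 2-fold limit for the MEF-high and ES-high sets, and a 2-fold limit for the genes shared by the iPS lines. A pseudocount of 1000 was chosen after seeing the data, because the signals proved large beside 16. The replicate numbers of the groups were not known to pair samples, and 6 of 15 arrays were closest to an array of their own number after group means were removed.

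The steps were tested in 5 simulations each with 200 of 18193 genes changed between CL11 and IP14D-101 or between IP14D-1 and IP20D-3. Their levels and spread were those of all groups, not of these pairs. For IP14D-101 against CL11, 19.6%, 42.4% and 57.4% of genes changed by 0.5, 1 and 2 log2 were recovered. Of 410 calls 14 (3.41%) were false. For IP20D-3 against IP14D-1 the shares were 20.3%, 42.9% and 61.0%, and 22 of 439 calls (5.01%) were false. In a test of 30 lists with 1 list shifted, the shifted list was called together with 1 other.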

Results

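Expression was compared between mouse embryonic fibroblasts (MEF), the embryonic stem (ES) cell line CL11 and the induced pluripotent stem (iPS) cell lines IP14D-1, IP14D-101 and IP20D-3, each on 3 arrays. Of 18193 genes, the share of values above background was 63.4% in MEF, 63.6% in CL11, 65.7% in IP14D-1, 63.0% in IP14D-101 and 64% in IP20D-3. The ratio of 3' to 5' actin signal, a measure of RNA degradation, was 1.16 ± 0.0185 in MEF, 1.21 ± 0.0184 in CL11, 1.37 ± 0.0365 in IP14D-1, 1.22 ± 0.0636 in IP14D-101 and 1.28 ± 0.0263 in IP20D-3 (standard deviation, n = 3). Arrays of the same group correlated at 0.941 to 0.954, and IP14D-101 replicate 3 had the lowest correlation with its own group, 0.944. Per the labels, only IP14D-101 has the C57x129S2 background, so in each of its comparisons line and background cannot be separated.

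To examine whether the ES and iPS lines had lost fibroblast identity and gained that of pluripotent cells, each line was compared with MEF. The transcription factor genes Pou5f1, Sox2 and Nanog lay below background in MEF and rose in every line. In CL11 they were at least 238-fold, 156-fold and 181-fold higher, in IP14D-1 at least 208-fold, 186-fold and 131-fold, in IP14D-101 at least 228-fold, 187-fold and 168-fold, and in IP20D-3 at least 227-fold, 192-fold and 153-fold. Klf4, already present in MEF, rose by 2.15 log2 in CL11, 2.07 in IP14D-1, 2.17 in IP14D-101 and 1.38 in IP20D-3 (standard error 0.10, n = 3 per group). Myc did not pass in CL11, IP14D-1 or IP14D-101 (0.05, −0.13 and 0.07 log2; adjusted p = 0.832, 0.592 and 0.777) and fell by 0.92 in IP20D-3 (adjusted p = 1.7e-04). Cdh1, which encodes E-cadherin, was at least 100-fold, 136-fold, 113-fold and 140-fold higher, in the order CL11, IP14D-1, IP14D-101 and IP20D-3 that is kept for all MEF comparisons.

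Among the genes named by the fixed rule for rises, Tdgf1 was at least 297-fold, 273-fold, 333-fold and 237-fold higher, Lin28a at least 106-fold, 134-fold, 117-fold and 142-fold, and Sall4 at least 121-fold, 122-fold, 110-fold and 131-fold. Of those named for falls, Postn was at least 448-fold lower in CL11, IP14D-101 and IP20D-3 and fell by 8.34 ± 0.70 log2 in IP14D-1. Col1a1, a collagen gene, was at least 417-fold lower in CL11, IP14D-101 and IP20D-3. In IP14D-1 it fell by 7.46 ± 0.56 log2 to a level of 12.28 ± 0.10, above background. Aspn was at least 124-fold lower in IP14D-1 and Pdgfrb at least 141-fold lower in IP20D-3.

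**Figure D1:**
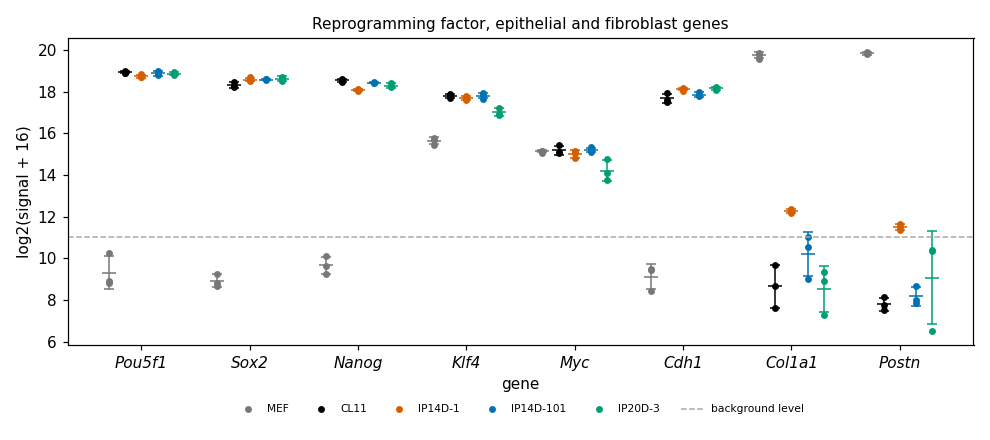
Log2(signal + 16) of Pou5f1, Sox2, Nanog, Klf4, Myc, Cdh1, Col1a1 and Postn in MEF, CL11, IP14D-1, IP14D-101 and IP20D-3. Points are arrays, bars are the mean and standard deviation of 3 arrays, and the dashed line is background at 11.04.

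In total 9837, 9600, 10017 and 9842 of 18193 genes changed against MEF. Of these, 5510, 5441, 5528 and 5538 were higher and 4327, 4159, 4489 and 4304 lower. At least 2-fold changes numbered 3468, 3367, 3490 and 3511 higher and 2895, 2657, 3052 and 2888 lower. Genes without overlap between the arrays numbered 11061, 11033, 10915 and 11012, where 10% would separate by chance. The dividing of 6 arrays as labelled gave the most changed genes in each comparison, and the highest other division gave 1 gene for CL11 and 0 for the iPS lines, but 10 splits are too few for a share under 0.05. Leaving out any array of the groups compared gave 9334 to 9465, 9034 to 9228, 9529 to 9681 and 9339 to 9473 genes. Median scaling moved the median change of all genes from 0.07 to 0.29 log2 in CL11 and from 0.05 to 0.39 in IP14D-101, and quantile normalization moved the latter to 0.21. The share of higher calls for IP14D-101 was 55.2%, and 67.3% under median scaling.

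All 34 members of the pluripotency network rose in every line (camera adjusted p = 3.7e-24, 7.8e-25, 1.4e-23 and 4.9e-24). Of 34 fibroblast and feeder matrix genes, 33, 34, 33 and 34 fell (adjusted p = 3.7e-24, 5.1e-24, 2.5e-23 and 2.5e-24). Mesenchymal transcription factors fell in 20, 18, 21 and 18 of 24 cases (adjusted p = 1.4e-07, 2.9e-07, 3.6e-08 and 1.6e-07), among them Prrx1 at least 64.3-fold in CL11. Among 25 epithelial junction genes, 23, 24, 23 and 23 rose (adjusted p = 1.9e-11, 1.1e-13, 2.5e-11 and 9.8e-13), and Epcam was at least 51.2-fold, 58.9-fold, 77.0-fold and 74.5-fold higher. Of 4 reprogramming factors 3 rose in every line and Myc fell in IP20D-3 (adjusted p = 0.00371, 0.00549, 0.00352 and 0.0256). In IP20D-3 this list had adjusted p = 0.0644 with an estimated correlation.

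Chromatin and DNA methylation enzymes rose in 30 of 31 cases in each line (adjusted p = 2.8e-15, 5.7e-15, 8.8e-15 and 1.2e-15), led by Dnmt3l at least 265-fold, 175-fold, 117-fold and 149-fold. Proliferation genes rose in 29, 29, 28 and 29 of 29 cases (adjusted p = 6.3e-17, 7.8e-16, 1.4e-16 and 8.0e-16), with Mybl2 higher by 5.65, 5.18, 5.05 and 5.67 log2. Germ line genes rose in 17, 16, 16 and 16 of 21 cases (adjusted p = 1.3e-05, 5.6e-06, 3.5e-05 and 2.4e-05), and Ddx4 was at least 12.6-fold, 11.3-fold, 10.4-fold and 7.05-fold higher. HOX genes fell in 22, 23, 26 and 25 of 28 cases (adjusted p = 4.1e-06, 3.1e-06, 3.7e-06 and 1.2e-06), and Hoxc8 was at least 32.7-fold lower in every line. Of 28 interferon response and class I MHC genes, 17, 14, 17 and 15 fell and 5, 6, 4 and 5 rose (adjusted p = 0.00366, 0.00983, 0.00309 and 0.00642), with B2m at −5.05, −3.98, −4.48 and −4.28 log2. LIF and STAT3 targets rose in 13, 12, 13 and 12 and fell in 7, 7, 7 and 8 of 21 cases (adjusted p = 0.00724, 0.0551, 0.00644 and 0.0635). Median scaling brought a call in IP14D-1 (adjusted p = 0.0331) and IP20D-3 (adjusted p = 0.0464), and pseudocounts of 64 and 1000 in IP14D-1 (adjusted p = 0.0491 and 0.0440).

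Of 16 primed epiblast genes, 11, 12, 12 and 12 rose and 3, 2, 3 and 2 fell (adjusted p = 0.00481, 6.6e-04, 0.00125 and 6.2e-04), Dnmt3b being at least 86.5-fold, 149-fold, 109-fold and 159-fold higher. None of these calls held, with adjusted p = 0.14, 0.0861, 0.105 and 0.0811 with an estimated correlation. Trophoblast genes rose in 11, 11, 9 and 11 of 18 cases, and Tfap2c was at least 19.6-fold, 17.3-fold, 22.9-fold and 28.4-fold higher. The list passed in CL11 (adjusted p = 0.0397) and IP20D-3 (adjusted p = 0.0318), with adjusted p = 0.0789 and 0.0644 with an estimated correlation, and not in IP14D-1 or IP14D-101 (adjusted p = 0.0551 and 0.197), though it passed in IP14D-1 under median scaling (adjusted p = 0.0347) and with pseudocounts of 64 and 1000 (adjusted p = 0.0491 and 0.0360). Endoderm genes rose in 13, 7, 12 and 6 and fell in 5, 9, 7 and 9 of 25 cases (adjusted p = 0.193, 0.192, 0.274 and 0.123). For mesoderm and primitive streak the counts were 7, 10, 7 and 7 up and 1, 2, 3 and 1 down of 21 (adjusted p = 0.561, 0.202, 0.606 and 0.667), and for neural ectoderm 6, 7, 7 and 6 up and 8, 8, 10 and 7 down of 23 (adjusted p = 0.471, 0.645, 0.478 and 0.684). Genes of the 2-cell-like state rose in 4, 4, 4 and 5 of 11 cases (adjusted p = 0.322, 0.167, 0.558 and 0.251).

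Imprinted and sex-linked genes were compared next. Meg3, a maternally expressed noncoding RNA of the Dlk1-Dio3 cluster, fell by 1.92, 1.02, 2.03 and 4.94 log2 (standard error 0.12). Rian fell by 0.95 log2 in CL11 and 0.97 in IP14D-101, did not pass in IP14D-1 (−0.44, adjusted p = 0.195) and was at least 12.2-fold lower in IP20D-3. Dlk1 fell by 1.89, 0.51, 0.83 and 2.11 log2 by a cross-hybridising probe set, the other lying below background. Of the 4 measured members of the cluster, 4, 2, 4 and 4 fell (adjusted p = 0.0204, 0.167, 0.0279 and 3.4e-04), with adjusted p = 0.09 in CL11, 0.105 in IP14D-101 and 0.0164 in IP20D-3 with an estimated correlation. Other imprinted genes rose in 9, 13, 9 and 12 and fell in 15, 10, 15 and 12 of 33 cases (adjusted p = 0.101, 0.728, 0.124 and 0.621), with Phlda2 at least 40.9-fold, 37.7-fold, 64-fold and 59.8-fold higher and Igf2 lower by −4.60, −4.41, −4.64 and −4.68 log2.

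Xist, RNA of the inactive X chromosome, was lower by 3.87, 3.26, 3.70 and 3.35 log2 (standard error 0.19) than 16.92 ± 0.22 in MEF. The sex of MEF is not given. The Y-linked genes Eif2s3y and Uty lay below background in MEF, and Eif2s3y was at least 8.5-fold, 24.1-fold, 8.89-fold and 25.1-fold and Uty at least 3.46-fold, 7.02-fold, 2.47-fold and 6.27-fold higher. Of the 5 sex-linked genes measured, 2, 3, 2 and 2 rose and 1 fell in each line (adjusted p = 0.687, 0.573, 0.823 and 0.689).

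**Figure D2:**
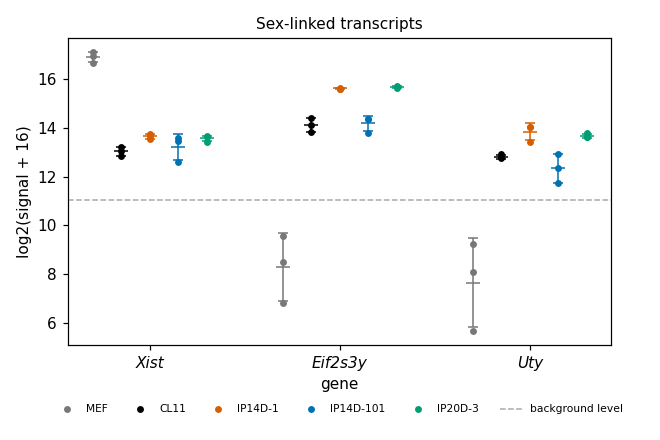
Log2(signal + 16) of Xist, Eif2s3y and Uty in the 5 groups. Points are arrays, bars are the mean and standard deviation of 3 arrays, and the dashed line is background at 11.04.

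Metabolic and stress lists were counted next. Amino acid and ER stress genes fell in 20, 10, 20 and 9 and rose in 2, 6, 1 and 6 of 25 cases, with Atf5 at −4.45, −3.60, −3.80 and −3.53 log2. The list passed in CL11 (adjusted p = 3.8e-06) and IP14D-101 (adjusted p = 1.3e-06), with adjusted p = 0.167 and 0.155 with an estimated correlation, and not in IP14D-1 or IP20D-3 (adjusted p = 0.167 and 0.212). Cholesterol synthesis genes fell in 10, 11, 6 and 11 and rose in 5, 1, 8 and 3 of 19 cases (adjusted p = 0.125, 0.00362, 0.705 and 0.0135). The calls in IP14D-1 and IP20D-3 had adjusted p = 0.313 and 0.421 with an estimated correlation. Oxidative phosphorylation genes rose in 22, 17, 25 and 16 and fell in 0, 2, 0 and 3 of 29 cases, a direction that flipped under no scaling (adjusted p = 8.0e-04, 0.0383, 1.5e-05 and 0.0318). The call in IP14D-1 was lost under median scaling (adjusted p = 0.144) and that in IP20D-3 under median scaling and quantile normalization (adjusted p = 0.0508 and 0.0539). With an estimated correlation these became adjusted p = 0.254, 0.495, 0.155 and 0.479. Hypoxia and glycolysis genes rose in 17, 10, 16 and 13 and fell in 8, 10, 8 and 10 of 27 cases (adjusted p = 0.311, 0.597, 0.195 and 0.948), Slc2a3 rising by 6.63, 6.56, 6.62 and 6.80 log2.

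The p53 and senescence list fell in 10, 10, 12 and 13 and rose in 6, 7, 6 and 4 of 21 cases (adjusted p = 0.0704, 0.167, 0.0279 and 0.00245), with adjusted p = 0.0567 in IP14D-101 and 0.0152 in IP20D-3 with an estimated correlation. Median scaling also ended the call in IP14D-101 (adjusted p = 0.0867), and quantile normalization brought one in CL11 (adjusted p = 0.0220). Immediate early and serum response genes fell in 17, 15, 16 and 15 and rose in 7, 8, 7 and 9 of 28 cases (adjusted p = 0.0401, 0.06, 0.0392 and 0.0815), and the calls in CL11 and IP14D-101 had adjusted p = 0.146 and 0.155 with an estimated correlation. Macrophage and blood genes fell in 11, 9, 11 and 11 and rose in 2, 2, 1 and 2 of 19 cases (adjusted p = 0.0401, 0.0514, 0.0241 and 0.0318), with C1qa at least 6.87-fold lower in CL11. The 3 calls had adjusted p = 0.0789, 0.0532 and 0.0644 with an estimated correlation. In IP14D-1 the list passed under quantile normalization and median scaling (adjusted p = 0.0464 and 0.0347) and with pseudocounts of 64 and 1000 (adjusted p = 0.0393 and 0.00321). Muscle, cartilage and endothelium genes rose in 7, 7, 7 and 6 and fell in 7, 6, 6 and 7 of 22 cases (adjusted p = 0.987, 0.777, 0.956 and 0.711). Ribosomal protein genes rose in 7, 5, 11 and 16 and fell in 2, 0, 1 and 0 of 19 cases, with no flip of direction under another scaling (adjusted p = 0.431, 0.395, 0.178 and 0.0135, the last with adjusted p = 0.472 with an estimated correlation). That call was also lost under quantile normalization (adjusted p = 0.583) and median scaling (adjusted p = 0.0650). Reference genes rose in 6, 5, 7 and 7 and fell in 2, 2, 3 and 2 of 11 cases, again without a flip under another scaling (adjusted p = 0.193, 0.395, 0.197 and 0.175).

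Of the 30 lists, 18, 13, 18 and 18 passed against MEF with the preset correlation and 11, 10, 11 and 11 with both settings. The calls of the pluripotency, fibroblast, mesenchymal, epithelial, germ line, chromatin, proliferation, interferon and HOX lists held in every line. Counts of members adjusted over the list alone were the same in 25, 21, 28 and 24 lists and otherwise moved by at most 2, 2, 1 and 3 members. Median, mean and test of a list differed in sign for neural ectoderm in CL11 (median 0.36 log2, mean 0.03, test down), IP14D-1 (−0.30, 0.30, down) and IP20D-3 (−0.05, 0.10, down). The same held for other imprinted genes and hypoxia genes in IP14D-1 and IP20D-3 and for muscle, cartilage and endothelium in IP14D-1 and IP14D-101, none of which passed.

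To place the iPS lines between MEF and the ES line, whole profiles were compared. Arrays of the iPS lines correlated with CL11 arrays at 0.927 to 0.943 and with MEF arrays at 0.780 to 0.808. The root mean square log2 difference from MEF, corrected for replicate spread, was 1.75 for CL11, 1.62 for IP14D-1, 1.75 for IP14D-101 and 1.74 for IP20D-3. From CL11 it was 0.581 for IP14D-1, 0.403 for IP14D-101 and 0.534 for IP20D-3, and between the iPS lines 0.608 for IP14D-101 and IP14D-1, 0.369 for IP20D-3 and IP14D-1 and 0.541 for IP20D-3 and IP14D-101. On the axis from MEF (0) to CL11 (1), IP14D-1 lay at 0.839 ± 0.0103, IP14D-101 at 0.931 ± 0.00621 and IP20D-3 at 0.907 ± 0.00873 (standard deviation, n = 3), where an unchanged ES line was calculated to lie at 0.951. The positions differed by 0.0912 between IP14D-101 and IP14D-1, by 0.0678 between IP20D-3 and IP14D-1 and by −0.0234 between IP20D-3 and IP14D-101, each with an exact 2-sided p of 0.1, the smallest possible with 3 against 3 arrays.

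**Figure D3:**
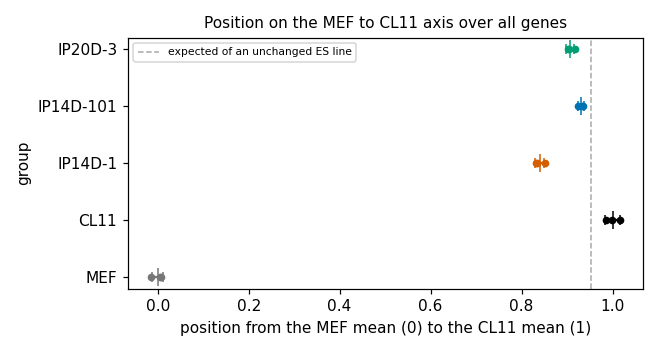
Position of each array on the axis from the MEF mean (0) to the CL11 mean (1), without unit, for MEF, CL11, IP14D-1, IP14D-101 and IP20D-3. Points are arrays, bars are the mean and standard deviation of 3 arrays, and the dashed line is the position calculated for an unchanged ES line, 0.951.

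IP14D-1 was then set against CL11. Pou5f1, Sox2, Klf4 and Myc did not pass (−0.19, 0.26, −0.08 and −0.18 log2; adjusted p = 0.623, 0.117, 0.632 and 0.529), nor did Cdh1 (0.44, adjusted p = 0.107), and Nanog fell by 0.47 log2 (adjusted p = 0.0144). The genes named for rises were Prex2 (at least 1.40-fold), Irs1 (at least 4.40-fold), Tnc (at least 3.86-fold), Ccn4 (at least 3.68-fold) and Prss23 (at least 12.9-fold), all below background in CL11. Those named for falls were Srgn (at least 50.6-fold), Cubn (at least 16.9-fold), Tfec (at least 4.16-fold), Nostrin (at least 2.69-fold) and Cyp4f14 (at least 2.42-fold). Meg3 rose by 0.90 log2 (adjusted p = 2.6e-05), Dlk1 by 1.38 (adjusted p = 5.7e-05) and Xist by 0.62 (adjusted p = 0.0248), the call for Xist being lost under median scaling. Rian did not pass (0.51, adjusted p = 0.201).

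Endoderm genes were lower in IP14D-1. Of 25 members 15 fell and 2 rose (16 and 4 adjusted over the list alone), with a median of −2.05 log2, and Gata6 was at least 13.4-fold lower (camera adjusted p = 1.2e-09). Amino acid and ER stress genes rose in 18 and fell in 2 of 25 cases (19 and 2 adjusted over the list alone; adjusted p = 4.8e-11), among them Vldlr at least 9.20-fold, Chac1 by 3.29, Ddit3 by 3.11 and Herpud1 by 2.62 log2. This call had adjusted p = 0.0956 with an estimated correlation. Hypoxia and glycolysis genes fell in 17 and rose in 1 of 27 cases, the same adjusted over the list alone (adjusted p = 2.9e-08; adjusted p = 0.0863 with an estimated correlation), with Egln3 lower by −1.90 and P4ha2 by −1.73 log2. Proliferation genes fell in 17 of 29 cases and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 2.3e-07), Aurkb by −1.02 log2, with adjusted p = 0.0956 with an estimated correlation. LIF and STAT3 targets fell in 8 of 21 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 4.8e-04), including Ier3 by −1.65 and Gbx2 by −1.51 log2.

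Fibroblast and feeder matrix genes rose in 16 and fell in 2 of 34 cases in IP14D-1 (18 and 2 adjusted over the list alone; adjusted p = 6.1e-08). Tagln rose by 3.56 ± 0.11 log2, Postn was at least 1.38-fold and Col1a1 at least 2.37-fold higher, and Pdgfra was at least 5.75-fold lower. For the 5 collagen genes called higher, the rise over CL11 had a median of 0.552% of their MEF level. The actin 3' to 5' ratio of IP14D-1 was the highest of the groups, 1.37. Epithelial junction genes rose in 11 of 25 cases (13 adjusted over the list alone; adjusted p = 3.3e-05; adjusted p = 0.0863 with an estimated correlation), with Rab25 up at least 3.07-fold, Dsp by 1.82 and Esrp1 by 1.47 log2. Other imprinted genes rose in 14 of 33 cases, the same adjusted over the list alone (adjusted p = 1.4e-05), among them Plagl1 by 3.56, Impact by 1.65 and Nnat by 1.38 log2. In the Dlk1-Dio3 cluster 2 of 4 members rose (3 adjusted over the list alone; adjusted p = 0.00504; adjusted p = 0.0863 with an estimated correlation). Primed epiblast genes rose in 9 and fell in 2 of 16 cases (10 and 2 adjusted over the list alone; adjusted p = 0.00105; adjusted p = 0.124 with an estimated correlation), with Nes at least 4.11-fold and Fgf5 at least 2.29-fold higher and Pou3f1 up by 1.57 log2.

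Chromatin enzymes fell in 14 and rose in 3 of 31 cases in IP14D-1, the same adjusted over the list alone (adjusted p = 0.00504; adjusted p = 0.124 with an estimated correlation), with Ehmt2 at −0.89, Dnmt3a at −0.87 and Dnmt3b at 0.78 log2, and lost the call under quantile normalization (adjusted p = 0.0659). Oxidative phosphorylation genes fell in 9 and rose in 1 of 29 cases, a direction that no scaling flipped (10 and 1 adjusted over the list alone; adjusted p = 0.00229; adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis genes fell in 7 and rose in 1 of 19 cases (adjusted p = 0.0423; adjusted p = 0.517 with an estimated correlation), a call also lost under quantile normalization (adjusted p = 0.0835). The pluripotency list did not pass (4 rose, 8 fell of 34; adjusted p = 0.373), with Lefty1 up by 2.33, Rex2 by 1.08 and Tfcp2l1 at −1.03 log2. Nor did immediate early genes (11 rose, 6 fell of 28; adjusted p = 0.0573), p53 and senescence genes (7 rose, 5 fell of 21; adjusted p = 0.32), mesoderm genes (6 rose, 1 fell of 21; adjusted p = 0.108), sex-linked genes (2 of 5 rose; adjusted p = 0.155) or reference genes (1 rose, 3 fell of 11; adjusted p = 0.658), whose median of −0.01 log2 flipped to 0.04 under quantile normalization. The immediate early list did pass under quantile normalization (adjusted p = 0.0399) and median scaling (adjusted p = 0.0478). Median scaling also brought a call for mesoderm (adjusted p = 0.0106), sex-linked and neural ectoderm genes (adjusted p = 0.0478 each), and the pseudocount of 1000 for mesoderm and sex-linked genes (adjusted p = 0.0488 and 0.0413). Atf3 rose by 2.56 log2 and Sp5 at least 12.3-fold. Of 13 lists called, 4 held with both settings, the fibroblast, other imprinted, endoderm and LIF lists. Signs of median, mean and test differed for the macrophage and ribosomal lists, which did not pass.

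Between IP14D-1 and CL11 4412 genes changed, 2128 higher (757 at least 2-fold) and 2284 lower (383 at least 2-fold). Under median scaling 1057 were higher and 3820 lower, the share of higher calls moving from 48.2% to 21.7% and the median of all genes from 0.03 to −0.22 log2. The split at 2-fold became 577 higher and 568 lower under quantile normalization and reversed to 473 and 770 under median scaling. Arrays did not overlap for 7473 genes, where 10% of genes would do so by chance. Other divisions of the arrays gave 0 genes, 10 splits being too few for a share under 0.05, and leaving out an array gave 3338 to 3933 genes.

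IP14D-101 differed least from CL11. Lefty1, a Nodal inhibitor gene, rose by 3.01 ± 0.10 log2, and Irs1 (at least 1.51-fold), Myh7 (at least 1.49-fold), Fn3krp (at least 1.31-fold) and Fgf22 (at least 1.04-fold) also rose. H2-Eb1 (at least 5.06-fold), Krtdap (at least 2.57-fold), Apoc2 (at least 9.76-fold), Vwa3b (at least 1.59-fold) and AI506816 (at least 8.32-fold) were named for falls. Dlk1 rose by 1.06 log2 (adjusted p = 0.00166), its other probe set lying below background in both lines. Pou5f1 (−0.06, adjusted p = 0.923), Sox2 (0.26, adjusted p = 0.17), Nanog (−0.10, adjusted p = 0.713), Meg3 (−0.11, adjusted p = 0.66) and Xist (0.17, adjusted p = 0.659) did not pass, and Klf4, Myc, Cdh1 and Rian were at 0.02, 0.02, 0.18 and −0.02 log2.

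Cholesterol synthesis genes rose in 11 of 19 cases in IP14D-101 (15 adjusted over the list alone; adjusted p = 2.6e-10), with Dhcr7 up by 1.13, Cyp51 by 1.04 and Msmo1 by 0.99 log2. Primed epiblast genes rose in 4 of 16 cases (6 adjusted over the list alone; adjusted p = 3.6e-04), Nes at least 2.76-fold, where its other probe set gave −0.09, and Sox4 by 0.68 log2. Endoderm genes fell in 5 and rose in 1 of 25 cases (7 and 1 adjusted over the list alone; adjusted p = 0.0125), with Thbd at least 1.01-fold higher, Amn at −0.83 and Rhox5 at −0.81 log2, and trophoblast genes fell in 2 of 18 cases (adjusted p = 0.0371), Tead4 by −1.46 log2. These 4 calls each had adjusted p = 0.174 with an estimated correlation, and the trophoblast call was lost under quantile normalization (adjusted p = 0.0656). Oxidative phosphorylation genes rose in 7 of 29 cases, a direction kept under each scaling (9 adjusted over the list alone; adjusted p = 0.0111; adjusted p = 0.53 with an estimated correlation), but the call was lost under quantile normalization (adjusted p = 0.211). Chromatin enzymes fell in 10 of 31 cases (adjusted p = 0.0371; adjusted p = 0.432 with an estimated correlation), a call also lost under median scaling (adjusted p = 0.324). None of the 6 list calls therefore held with both settings.

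Other lists did not pass in IP14D-101. The pluripotency network had 2 of 34 members up and 4 down (3 and 6 adjusted over the list alone; adjusted p = 0.713), with Zfp42 at 1.78 and Dnmt3l at −1.18 log2. For the fibroblast list 6 rose and 2 fell of 34 (8 and 4 adjusted over the list alone; adjusted p = 0.308), with Acta2 at 1.29 log2 from a probe set that cross-hybridises by name, its other probe sets lying below background in both lines. Epithelial junction genes rose in 6 and fell in 3 of 25 cases (7 and 4 adjusted over the list alone; adjusted p = 0.406), Rab25 at least 2.32-fold higher and Krt19 at least 1.88-fold lower. In the Dlk1-Dio3 cluster 1 of 4 rose (adjusted p = 0.855), and of other imprinted genes 8 rose and 4 fell of 33 (9 and 6 adjusted over the list alone; adjusted p = 0.308), Grb10 at −1.76 log2. Reference genes rose in 3 and fell in 1 of 11 cases (adjusted p = 0.308), with no flip under another scaling. The signs of median, mean and test were not all alike for the pluripotency, Dlk1-Dio3, other imprinted, neural ectoderm and LIF lists.

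In all, 2092 genes changed between IP14D-101 and CL11, 1100 higher (167 at least 2-fold) and 992 lower (253 at least 2-fold). Median scaling gave 1170 higher and 451 lower, a share of 72.2% against 52.6%, and moved the median of all genes from 0.00 to 0.12 log2. At 2-fold, 188 were higher and 200 lower under quantile normalization, and the split reversed to 227 and 181 under median scaling. Arrays did not overlap for 5137 genes against 10% by chance. The highest other division of arrays gave 1 gene, with 10 splits too few for a share under 0.05. Without CL11 replicate 2 the count was 1386, and the highest count without an array was 1950.

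IP20D-3 was next set against CL11. Meg3 fell by 3.02 ± 0.12 log2, 8.13-fold (adjusted p = 1.5e-11), Mirg by 2.62 log2, and Rian was at least 6.30-fold lower, while Dlk1 did not pass (−0.22, adjusted p = 0.506). Klf4 fell by 0.77 log2 (adjusted p = 2.1e-05) and Myc by 0.98 (adjusted p = 5.0e-04). Pou5f1 was at −0.07, Sox2 at 0.30 (adjusted p = 0.0719), Nanog at −0.24 (adjusted p = 0.227), Cdh1 at 0.48 (adjusted p = 0.0796) and Xist at 0.53 log2 (adjusted p = 0.0586). Vldlr (at least 7.42-fold), Irs1 (at least 1.98-fold), Lrrn1 (at least 1.20-fold), AI662270 (at least 11.5-fold) and Rab25 (at least 5.48-fold) rose. Srgn (at least 50.6-fold), Tfec (at least 4.16-fold), Cubn (at least 16.9-fold), Nostrin (at least 2.69-fold) and Pdgfra (at least 5.75-fold) were lower by the same bounds as in IP14D-1.

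**Figure D4:**
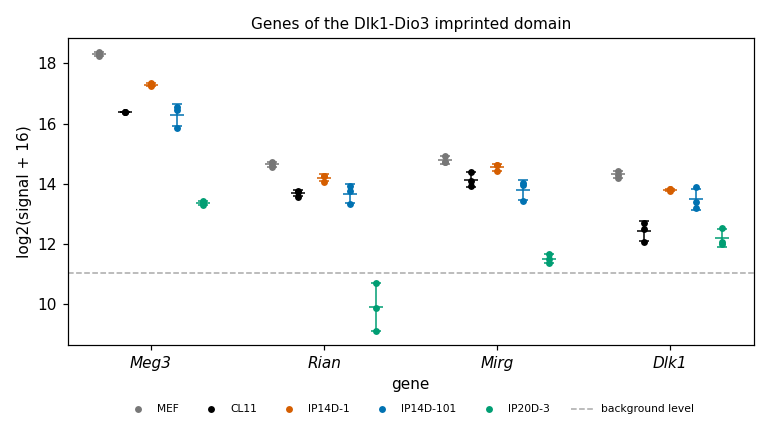
Log2(signal + 16) of Meg3, Rian, Mirg and Dlk1 in the 5 groups. Points are arrays, bars are the mean and standard deviation of 3 arrays, and the dashed line is background at 11.04.

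Of the 4 Dlk1-Dio3 members 3 fell in IP20D-3 (adjusted p = 2.0e-06, and 0.0123 with an estimated correlation). Endoderm genes fell in 16 and rose in 3 of 25 cases, the same adjusted over the list alone (adjusted p = 2.7e-11). Amino acid and ER stress genes rose in 19 and fell in 2 of 25 cases (20 and 2 adjusted over the list alone; adjusted p = 5.6e-13), Ddit3 by 3.10, Chac1 by 2.68 and Nupr1 by 2.61 log2, with adjusted p = 0.0991 with an estimated correlation. Other imprinted genes rose in 9 of 33 cases, the same adjusted over the list alone (adjusted p = 4.8e-04), Impact by 1.54 and Plagl1 by 2.53 log2. The p53 and senescence genes fell in 10 and rose in 4 of 21 cases, the same adjusted over the list alone (adjusted p = 5.4e-04), among them Cdkn1a by −1.08 and Plk2 by −0.99 log2. LIF and STAT3 targets fell in 8 and rose in 2 of 21 cases (9 and 2 adjusted over the list alone; adjusted p = 0.0075), Gbx2 by −2.60 and Ier3 by −2.01 log2.

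Epithelial junction genes rose in 11 of 25 cases in IP20D-3 (13 adjusted over the list alone; adjusted p = 1.2e-04; adjusted p = 0.111 with an estimated correlation), Cldn7 by 1.70 and Esrp1 by 1.65 log2. Primed epiblast genes rose in 10 of 16 cases (adjusted p = 4.8e-04; adjusted p = 0.133 with an estimated correlation), Nes at least 4.61-fold. Hypoxia and glycolysis genes fell in 14 and rose in 1 of 27 cases (14 and 2 adjusted over the list alone; adjusted p = 1.2e-04; adjusted p = 0.211 with an estimated correlation), P4ha2 by −2.28 and Egln3 by −1.78 log2. Proliferation genes fell in 10 and rose in 2 of 29 cases (12 and 2 adjusted over the list alone; adjusted p = 0.00914; adjusted p = 0.467 with an estimated correlation), Aurkb by −1.06 log2. Ribosomal protein genes rose in 4 of 19 cases, and the median of the list kept its sign under each scaling although Rps6, Rpl10a, Rpl4 and Rps3 no longer passed under median scaling (10 adjusted over the list alone; adjusted p = 1.2e-04; adjusted p = 0.408 with an estimated correlation). The call of the list was lost under quantile normalization (median 0.02 log2, adjusted p = 0.461) and median scaling (adjusted p = 0.0616). Oxidative phosphorylation genes fell in 9 and rose in 2 of 29 cases, with no flip under another scaling (10 and 2 adjusted over the list alone; adjusted p = 0.0462; adjusted p = 0.654 with an estimated correlation), and lost the call under quantile normalization (adjusted p = 0.0614).

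The fibroblast list did not pass in IP20D-3 (8 rose, 6 fell of 34, the same adjusted over the list alone; adjusted p = 0.646), with Cnn1 at least 3.57-fold higher and Tagln up by 2.09 log2. Neither did the pluripotency network (4 rose, 5 fell of 34; 5 and 7 adjusted over the list alone; adjusted p = 0.868), with Lefty1 at 1.76, Nr5a2 at −1.42, Tex19.1 at −1.28 and Dppa3 at 1.05 log2, nor reprogramming factors (2 of 4 fell; adjusted p = 0.203). Chromatin enzymes (4 rose, 7 fell of 31; adjusted p = 0.929), immediate early genes (8 rose, 3 fell of 28; adjusted p = 0.153) and neural ectoderm genes (6 rose, 3 fell of 23; adjusted p = 0.328) did not pass either, with Sox1 at least 3.12-fold lower and Sox11 at 1.43 log2. Of 12 lists called, 5 held with both settings, the Dlk1-Dio3, other imprinted, endoderm, p53 and LIF lists. Median and test differed in sign for the mesenchymal and mesoderm lists, which did not pass. Cholesterol genes passed under median scaling (adjusted p = 0.0457) and sex-linked genes with the pseudocount of 1000 (adjusted p = 0.00792).

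Changed genes between IP20D-3 and CL11 numbered 3984, with 1920 higher (529 at least 2-fold) and 2064 lower (442 at least 2-fold). Under median scaling the numbers were 1054 and 2369, a share of higher calls of 30.8% against 48.2%, and the median of all genes moved from 0.02 to −0.11 log2. The 2-fold split reversed to 447 higher and 519 lower under quantile normalization and to 380 and 587 under median scaling. Arrays did not overlap for 6891 genes against 10% by chance, other divisions gave 0 genes with 10 splits too few for a share under 0.05, and leaving out an array gave 3054 to 3439 genes.

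**Figure D5:**
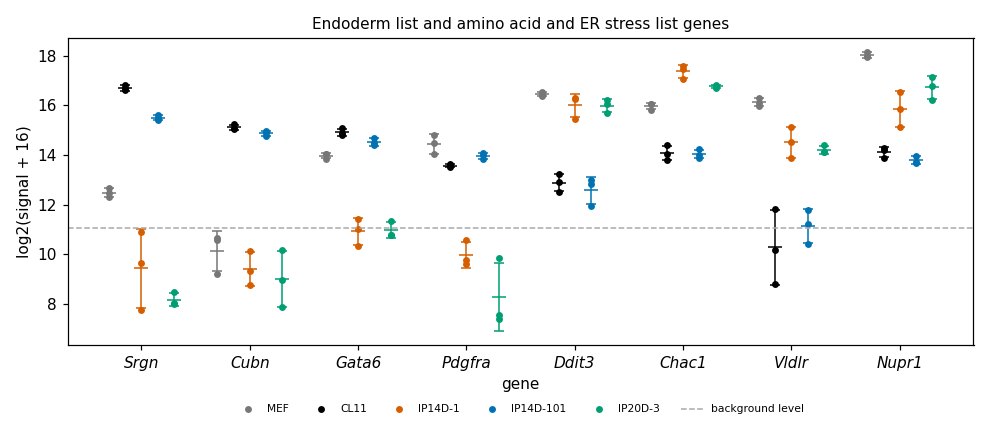
Log2(signal + 16) of Srgn, Cubn, Gata6, Pdgfra, Ddit3, Chac1, Vldlr and Nupr1 in the 5 groups. Points are arrays, bars are the mean and standard deviation of 3 arrays, and the dashed line is background at 11.04.

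Genes that differed from CL11 in the same direction in all 3 iPS lines were then collected, and those named here were chosen after their values were seen. Nes was at least 4.11-fold higher in IP14D-1, 2.76-fold in IP14D-101 and 4.61-fold in IP20D-3, and Rab25 was at least 3.07-fold, 2.32-fold and 5.48-fold higher. Lefty1 rose by 2.33, 3.01 and 1.76 log2. Plet1 fell by 2.83, 2.33 and 1.81 log2, though another probe set gave 0.25 in IP14D-101, and Tafa1 was at least 1.90-fold, Hkdc1 at least 2.12-fold and Vwa3b at least 1.59-fold lower in each. Together 342 genes were higher (69 at least 2-fold) and 303 lower (38 at least 2-fold). Independent lists would share 13.6 and 14.1 genes. In 20 simulations in which the called differences were dealt to other genes and only the CL11 values were shared, the mean counts were 25.9 and 28.8 and the highest 32 and 38. The simulated lists held 3693, 1620 and 3297 changed genes in the mean, fewer than the measured 4412, 2092 and 3984. CL11 was the only ES line, so part of the excess may come from expression peculiar to CL11 itself. Leaving out an array gave 441 to 524 genes.

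The iPS lines were then compared in pairs. Between IP14D-101 and IP14D-1, Srgn (at least 21.9-fold), Cubn (at least 14.2-fold), Pdgfra (at least 7.56-fold), Cyp4f14 (at least 1.67-fold) and Tfec (at least 1.52-fold) were higher in IP14D-101. Mmp13 (at least 1.13-fold), Ankrd31 (at least 6.65-fold), Trim66 (at least 1.22-fold), Ptgs2 (at least 6.91-fold) and Mid1 (−4.48 ± 0.18 log2) were lower, as was Col1a1 (at least 2.37-fold). Meg3 fell by 1.01 log2 (adjusted p = 6.4e-06) and Nanog rose by 0.36 (adjusted p = 0.0491). Rian (−0.53, adjusted p = 0.164), Dlk1 (−0.32, adjusted p = 0.277) and Xist (−0.44, adjusted p = 0.099) did not pass.

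Of the 1585 MEF-high genes 412 fell and 81 rose in IP14D-101 against IP14D-1 (median −0.42 log2, camera p = 8.2e-08, and 4.6e-04 with an estimated correlation), and of the 1621 ES-high genes 329 rose and 181 fell (median 0.14 log2, p = 0.0251, and 0.0292 with an estimated correlation), a call lost under quantile normalization (p = 0.0901). Fibroblast and feeder matrix genes fell in 21 and rose in 1 of 34 cases (23 and 2 adjusted over the list alone; adjusted p = 6.4e-07), Lox at least 6.08-fold. Endoderm genes rose in 16 and fell in 4 of 25 cases, the same adjusted over the list alone (adjusted p = 4.0e-07), Gata6 at least 10.2-fold. Other imprinted genes fell in 12 and rose in 2 of 33 cases, the same adjusted over the list alone (adjusted p = 0.0048), Grb10 by −2.33 and Peg3 by −2.07 log2, and their median of −0.33 was 0.03 under median scaling with the call kept (adjusted p = 0.0102). LIF and STAT3 targets rose in 9 and fell in 3 of 21 cases (9 and 4 adjusted over the list alone; adjusted p = 0.00426), Gbx2 by 1.66 and Socs3 by 1.14 log2. These 4 lists held with both settings, out of 13 called.

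Cholesterol synthesis genes rose in 16 of 19 cases in IP14D-101 against IP14D-1 (18 adjusted over the list alone; adjusted p = 1.7e-10), Dhcr7 by 1.39 and Fdps by 1.20 log2, and hypoxia and glycolysis genes rose in 19 and fell in 3 of 27 (21 and 4 adjusted over the list alone; adjusted p = 3.8e-07), Egln3 and P4ha1 by 1.68 log2 each. Both had adjusted p = 0.106 with an estimated correlation. Amino acid and ER stress genes fell in 16 and rose in 3 of 25 cases (19 and 3 adjusted over the list alone; adjusted p = 1.6e-09), Ddit3 by −3.41 and Chac1 by −3.32 log2, and proliferation genes rose in 18 and fell in 3 of 29 (20 and 3 adjusted over the list alone; adjusted p = 6.9e-07), Aurkb by 1.03 and E2f1 by 0.89 log2. Each had adjusted p = 0.114 with an estimated correlation, as did the Dlk1-Dio3 cluster, in which 2 of 4 fell (adjusted p = 0.0217), Mirg by −0.75 log2. Oxidative phosphorylation genes rose in 17 and fell in 1 of 29 cases, with no flip under another scaling (19 and 1 adjusted over the list alone; adjusted p = 1.0e-06; adjusted p = 0.168 with an estimated correlation), Uqcrh by 0.86 log2.

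Epithelial junction genes fell in 8 of 25 cases in IP14D-101 against IP14D-1 (adjusted p = 0.0143; adjusted p = 0.211 with an estimated correlation), Krt19 at least 3.42-fold, Dsp by −2.22 and Krt8 by −1.77 log2, and their median of −0.24 was 0.12 under median scaling. Mesenchymal transcription factors fell in 5 of 24 cases (adjusted p = 0.0217; adjusted p = 0.106 with an estimated correlation), Fosl2 at least 2.47-fold and Cebpb by −1.52 log2, a call lost under quantile normalization (adjusted p = 0.0737). The p53 and senescence genes fell in 7 and rose in 3 of 21 cases (adjusted p = 0.0433; adjusted p = 0.106 with an estimated correlation), Sesn2 by −1.19 log2, and the list did not pass under median scaling (adjusted p = 0.181), where its median was 0.16 instead of −0.20. The pluripotency network (7 rose, 5 fell of 34; adjusted p = 0.556), primed epiblast (2 rose, 4 fell of 16; adjusted p = 0.472), chromatin enzymes (7 rose, 4 fell of 31; adjusted p = 0.568), immediate early genes (5 rose, 9 fell of 28; adjusted p = 0.126) and reference genes (3 rose, 2 fell of 11 with no flip under another scaling; adjusted p = 0.267) did not pass. Rex2 was at −1.85, Zfp42 at 1.75 and Fgf4 at 1.09 log2. Median and mean differed in sign for the chromatin, interferon and muscle lists, none of which passed. Under median scaling the chromatin list passed (median 0.34 instead of −0.02 log2, adjusted p = 0.0289), as did the reference and 2-cell-like lists (adjusted p = 0.0186 each) and the mesoderm, ribosomal and sex-linked lists (adjusted p = 0.0170, 0.0220 and 0.0294). The pseudocount of 1000 brought calls for the mesoderm and sex-linked lists (adjusted p = 0.0495 and 0.0172).

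Changed genes in IP14D-101 against IP14D-1 numbered 5085, 2706 higher (337 at least 2-fold) and 2379 lower (915 at least 2-fold). The share of higher calls was 53.2%, and 83.9% under median scaling, which moved the median of all genes from −0.04 to 0.32 log2, while quantile normalization moved it to 0.12. At 2-fold, 630 were higher and 622 lower under quantile normalization, and 1296 and 506 under median scaling, so the split reversed under both. Arrays did not overlap for 7539 genes against 10% by chance, other divisions gave 0 genes with 10 splits too few for a share under 0.05, and leaving out an array gave 4027 to 4930 genes.

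IP20D-3 and IP14D-1 share their background per the labels and were closest to each other. Meg3 fell in IP20D-3 by 3.93 ± 0.12 log2, 15.2-fold (adjusted p = 6.7e-13), Mirg by 3.03 log2, Dlk1 3.04-fold (adjusted p = 4.9e-05), and Rian was at least 8.97-fold lower. Cap1 fell by 4.58 ± 0.19 log2, Col8a1 was at least 2.65-fold and Tmem87a at least 6.84-fold lower, and Col1a1 was at least 2.37-fold lower. AI662270 (at least 12.8-fold), Usp26 (at least 4.29-fold), Il17b (at least 2.55-fold), Pla2g2e (at least 1.01-fold) and Pnma5 (2.59 ± 0.18 log2) were higher. Klf4 fell by 0.69 log2 (adjusted p = 2.6e-04) and Myc by 0.80 (adjusted p = 0.00789), while Pou5f1, Sox2, Cdh1 and Xist were at 0.13, 0.04, 0.04 and −0.09 log2 and Nanog at 0.22 (adjusted p = 0.361), none of which passed.

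All 4 Dlk1-Dio3 members fell in IP20D-3 against IP14D-1 (adjusted p = 4.0e-15). Fibroblast and feeder matrix genes fell in 19 and rose in 1 of 34 cases (22 and 2 adjusted over the list alone; adjusted p = 2.8e-15). Col3a1 was at least 3.22-fold lower and Acta2 fell by 2.70 log2, the other probe sets of both genes lying below background in these lines. The p53 and senescence genes fell in 12 of 21 cases (14 adjusted over the list alone, with 1 up; adjusted p = 1.0e-12), Cdkn2b by −2.18, Cdkn1a by −1.17 log2 and Cdkn2a at least 1.96-fold, the call for Cdkn2a being lost under median scaling. These 3 of 7 called lists held with both settings. Of the MEF-high genes 226 fell and 25 rose (median −0.34 log2, camera p = 4.8e-10, and 1.5e-04 with an estimated correlation), and of the ES-high genes 151 rose and 60 fell (median 0.12 log2, p = 0.00177, and 0.00528 with an estimated correlation).

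Ribosomal protein genes rose in 8 of 19 cases in IP20D-3 against IP14D-1, Rps6 by 0.43 log2 (12 adjusted over the list alone; adjusted p = 7.6e-07), and proliferation genes rose in 8 of 29 (11 adjusted over the list alone; adjusted p = 2.1e-04). Both had adjusted p = 0.228 with an estimated correlation, and the ribosomal call was lost under quantile normalization (median 0.03 log2, adjusted p = 0.782). Chromatin enzymes rose in 6 of 31 cases (adjusted p = 2.7e-04; adjusted p = 0.103 with an estimated correlation), Phf19 by 1.37 log2. Mesoderm and primitive streak genes fell in 3 and rose in 1 of 21 cases (4 and 1 adjusted over the list alone; adjusted p = 0.0497; adjusted p = 0.173 with an estimated correlation), Sp5 by −3.46 log2, a call lost under quantile normalization (adjusted p = 0.0988) and with a pseudocount of 1 (adjusted p = 0.0549). The pluripotency network did not pass (6 rose, 3 fell of 34; adjusted p = 0.484), Dppa3 being at 1.07 log2, and neither did the epithelial list (1 rose, 3 fell of 25; adjusted p = 0.992), Krt8 at −1.25 log2. Reprogramming factors (2 of 4 fell; adjusted p = 0.0906), hypoxia genes (6 rose, 3 fell of 27; adjusted p = 0.0906), immediate early genes (5 rose, 8 fell of 28; adjusted p = 0.212) and LIF targets (6 rose, 3 fell of 21; adjusted p = 0.656) did not pass. Median scaling brought calls for the endoderm and HOX lists (adjusted p = 0.0458 each) and the mesenchymal list (adjusted p = 0.0217). For the epithelial list (median 0.05 log2, mean −0.02) and LIF targets (0.11 and −0.01) median and mean differed in sign.

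In this comparison 1672 genes changed, 886 higher (85 at least 2-fold) and 786 lower (231 at least 2-fold), a share of higher calls of 52.99% that was 72.5% under median scaling. Arrays did not overlap for 5234 genes against 10% by chance, and other divisions of the arrays gave 0 genes, with 10 splits too few for a share under 0.05. Without the variance trend 1025 genes changed, and leaving out an array gave 1013 to 1285.

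IP20D-3 was last set against IP14D-101. AI662270 (at least 12.8-fold), Trim66 (at least 1.33-fold), Mid1 (4.51 ± 0.18 log2), Ankrd31 (at least 5.05-fold) and Usp26 (at least 4.29-fold) were higher in IP20D-3, and Srgn (at least 21.9-fold), Cubn (at least 14.2-fold), Pdgfra (at least 7.56-fold), Tfec (at least 1.52-fold) and Nostrin (at least 1.28-fold) were lower. Meg3 fell by 2.92 log2, Mirg by 2.28 and Dlk1 by 1.29 (its other probe set lying below background), and Rian was at least 6.21-fold lower. Klf4 fell by 0.79 and Myc by 0.99 log2.

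All 4 Dlk1-Dio3 members fell in IP20D-3 against IP14D-101 (adjusted p = 4.9e-08) and endoderm genes fell in 16 and rose in 2 of 25 cases (17 and 2 adjusted over the list alone; adjusted p = 1.7e-09), Gata6 at least 10.4-fold, and these 2 of 13 called lists held with both settings. Amino acid and ER stress genes rose in 17 and fell in 2 of 25 cases (19 and 3 adjusted over the list alone; adjusted p = 9.5e-12), Ddit3 by 3.40 and Vldlr by 3.05 log2, and cholesterol synthesis genes fell in 17 of 19 (17 and 1 up adjusted over the list alone; adjusted p = 8.3e-10), Msmo1 by −1.22 and Fdps by −1.21 log2. Other imprinted genes rose in 10 and fell in 5 of 33 cases (11 and 5 adjusted over the list alone; adjusted p = 0.0458), Grb10 by 2.39 and Peg3 by 1.99 log2, a call lost with the pseudocount of 1000 (adjusted p = 0.0558). Trophoblast genes rose in 4 of 18 cases (adjusted p = 0.0249), Rhox6 by 2.28 and Rhox9 by 1.86 log2, and p53 and senescence genes fell in 9 and rose in 2 of 21 (9 and 4 adjusted over the list alone; adjusted p = 0.0153), Sesn1 by −1.11 log2. These 5 lists each had adjusted p = 0.0937 with an estimated correlation.

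Hypoxia and glycolysis genes fell in 13 and rose in 3 of 27 cases in IP20D-3 against IP14D-101 (14 and 4 adjusted over the list alone; adjusted p = 1.0e-04), P4ha1 by −1.80 log2, and epithelial junction genes rose in 8 of 25 (10 adjusted over the list alone, with 1 down; adjusted p = 0.00206), Dsp by 1.65 log2. Both had adjusted p = 0.182 with an estimated correlation. Oxidative phosphorylation genes fell in 14 and rose in 1 of 29 cases (15 and 1 adjusted over the list alone; adjusted p = 3.2e-05; adjusted p = 0.251 with an estimated correlation). LIF and STAT3 targets fell in 10 and rose in 3 of 21 cases, the same adjusted over the list alone (adjusted p = 0.00867; adjusted p = 0.0803 with an estimated correlation), Gbx2 by −2.74 log2. Proliferation genes fell in 12 and rose in 4 of 29 cases (14 and 4 adjusted over the list alone; adjusted p = 0.00708; adjusted p = 0.359 with an estimated correlation). Ribosomal protein genes rose in 2 of 19 cases, but the median of the list, 0.13 log2, flipped to −0.11 under median scaling (adjusted p = 0.00981; adjusted p = 0.493 with an estimated correlation). The call was lost under median scaling (adjusted p = 0.800) and quantile normalization (adjusted p = 0.290).

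The fibroblast list did not pass between IP20D-3 and IP14D-101 (7 rose, 8 fell of 34; 10 and 10 adjusted over the list alone; adjusted p = 0.951), nor did the pluripotency network (7 rose, 4 fell of 34; 7 and 6 adjusted over the list alone; adjusted p = 0.992), with Zfp42 at −2.08 and Rex2 at 1.32 log2. Reprogramming factors (2 of 4 fell; adjusted p = 0.0856), chromatin enzymes (9 rose, 4 fell of 31; adjusted p = 0.0698) and immediate early genes (6 rose, 5 fell of 28; adjusted p = 0.4) did not pass. The chromatin list did pass under quantile normalization (adjusted p = 0.00296) and with the pseudocount of 1000 (adjusted p = 0.0489), reprogramming factors under median scaling (adjusted p = 0.0471), and sex-linked genes with the pseudocount of 1000 (adjusted p = 0.00246). The median, mean and test differed in sign for the pluripotency (−0.01 and −0.05 log2, test up), fibroblast (0.08 and −0.08, test down), mesoderm and reference lists. MEF-high genes rose in 218 and fell in 144 cases (median 0.10 log2, camera p = 0.164, and 0.214 with an estimated correlation), and ES-high genes rose in 212 and fell in 232 (median −0.02 log2, p = 0.869, and 0.855 with an estimated correlation).

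A total of 4274 genes changed between IP20D-3 and IP14D-101, 2008 higher (621 at least 2-fold) and 2266 lower (331 at least 2-fold). The share of higher calls was 47.0%, and 19.7% under median scaling, which moved the median of all genes from 0.01 to −0.23 log2, while quantile normalization moved it to −0.09. At 2-fold the split reversed to 455 higher and 471 lower under quantile normalization and to 366 and 727 under median scaling. Arrays did not overlap for 6518 genes against 10% by chance. The highest other division of the arrays gave 3 genes, with 10 splits too few for a share under 0.05, and leaving out an array gave 3380 to 4123 genes.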

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

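Lower Meg3, Rian and Mirg in IP20D-3 than in IP14D-1 was weighed by probe set and flanking gene tests set before the values were seen. A strain variant test was chosen only after the result was seen. The 4 Dlk1-Dio3 transcripts had a median change of −3.48 log2 here and −2.60 against IP14D-101, neither predicted. Against a faulty probe set, 12 of 14 other probe sets of these genes (85.7%) were also lower in IP20D-3, and against loss of a longer segment, the 10 flanking genes had a median change of 0.15 log2 (interquartile range −0.14 to 0.20), with 0 lower and 1 (Mok) higher. Against a strain variant under some probes, the same 85.7%, spread over the genes, were lower. Silencing of the maternal copy in IP20D-3 or a loss within the cluster, unseen by flanking genes, may remain. Silencing alone would not lower the paternally expressed Dlk1, by a cross-hybridising probe set 3.04-fold lower than in IP14D-1. Dlk1 also fell against IP14D-101 but did not pass against CL11 (12.20 and 12.42 log2). DNA methylation was not measured and each line was derived once.

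The higher fibroblast list in IP14D-1 than in CL11 was weighed with a test of array scaling set before the values were seen and with feeder tests chosen only after the result was seen. Against feeders with the MEF profile as the only source, the rise over CL11 ran from 0.285% (Postn) to 15.9% (Tagln) of the MEF level. Over 16 raised members the ratio was 55.6 around a median of 1.19%, with Acta2 at 9.12%. For the 5 collagen genes alone this rise ran from 0.360% to 0.748%, a ratio of 2.07 around a median of 0.552%, which a small carry-over of feeder or unconverted fibroblasts could give. Array scaling was argued against, because the list stayed higher under quantile normalization and median scaling, the higher adjusted camera p being 2.2e-07. A mixture of carried-over cells for the collagens with line-specific expression of Tagln and Acta2 may remain, as may feeders unlike MEF. No cell counts separate them.

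Y-linked Eif2s3y and Uty at background in MEF and present in all 4 lines were weighed with tests chosen only after the result was seen. The last of 3 feeder tests followed those with Col1a1 and with 29 abundant fibroblast genes, which had left the matter open. The feeder level of Eif2s3y needed lay above the highest gene in MEF by 2.51 log2 by 7 collagens (95% interval 0.32 to 2.69, genes and arrays drawn again) and by 0.70 by the 29 genes (−0.15 to 1.31), but male feeders stayed open, as both assume the MEF profile. Against a mislabelled MEF group, 33 fibroblast list members were higher in MEF than in CL11. MEF from other animals than those behind the lines may remain. In MEF 0 Y-linked transcripts lay above background on all arrays, and Xist was highest. The sex of the embryos is not given and may differ in each MEF comparison.

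The fibroblast list was also lower in IP14D-101 than in IP14D-1, with a median of −0.94 log2 that had not been predicted. In IP20D-3 against IP14D-1 the same list had a median of −0.65 log2, again without a prediction. Other imprinted genes had a median of −0.33 log2 in IP14D-101 against IP14D-1. Endoderm genes had a median of 1.25 log2 in IP14D-101 against IP14D-1. The endoderm list had a median of −1.69 log2 in IP20D-3 against IP14D-101. LIF and STAT3 targets had a median of 0.27 log2 in IP14D-101 against IP14D-1. The p53 and senescence list had a median of −0.39 log2 in IP20D-3 against IP14D-1. Of 9160 probe sets without a gene name, 78 lay above background on all 12 ES and iPS arrays and on no MEF array, and they were left unread.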

How the results depend on the processing

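The number of changed genes stayed within 1.5 times its first value in all 10 comparisons under pseudocounts of 1, 64 and 1000, quantile normalization, median scaling, leaving out dim genes, leaving out cross-hybridising probe sets and fitting only the groups compared. The pseudocount of 1000, chosen after seeing the data, gave 10101, 9918, 10192 and 10091 genes against MEF for CL11, IP14D-1, IP14D-101 and IP20D-3. It gave 4808, 2311 and 4305 genes against CL11 for IP14D-1, IP14D-101 and IP20D-3, then 5445 for IP14D-101 against IP14D-1, 1920 for IP20D-3 against IP14D-1 and 4524 for IP20D-3 against IP14D-101. Testing all probe sets instead of the brightest tested more features, with counts of 19552, 18914, 20578 and 19746 against MEF, 7747, 3232 and 6520 against CL11, 10556 for IP14D-101 against IP14D-1 and 8188 for IP20D-3 against IP14D-101. The split into higher and lower turned over for IP14D-101 against MEF (9832 and 10746), the lines against CL11 (4243 and 3504, 1492 and 1740, 3428 and 3092), IP14D-101 against IP14D-1 (4282 and 6274) and IP20D-3 against IP14D-101 (4735 and 3453), and at 2-fold for CL11 (6304 and 7007) and IP14D-101 (6232 and 8027) against MEF. Without the variance trend the count for IP20D-3 against IP14D-1 was 1025 instead of 1672. Leaving out IP14D-1 replicate 1, IP14D-1 replicate 2 or IP20D-3 replicate 1 gave 1017, 1013 and 1084 genes there and the highest count without an array was 1285, and leaving out CL11 replicate 2 gave 1386 instead of 2092 for IP14D-101 against CL11, where the highest such count was 1950. The cause was not tested.

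The replicate block gave 9803, 9555, 9972 and 9788 changed genes against MEF, 4298, 1994 and 3854 against CL11, and 5021, 1534 and 4208 between the iPS lines. Genes shared by the iPS lines against CL11 numbered 613 with the block, and the median changes of the MEF-high sets were −0.42, −0.34 and 0.10 and those of the ES-high sets 0.14, 0.12 and −0.01, in the order IP14D-101 against IP14D-1, IP20D-3 against IP14D-1 and IP20D-3 against IP14D-101. Of 300 list results 296 were unchanged by the block and of 942 results for named genes 934. Calls lost with the block were those of mesoderm genes in IP20D-3 against IP14D-1 (adjusted p = 0.0602) and other imprinted genes in IP20D-3 against IP14D-101 (adjusted p = 0.0584), and calls gained with the block were macrophage and trophoblast genes in IP14D-1 against MEF (adjusted p = 0.0463 each). The numbers of the replicates are not known to pair samples, and the correlation of arrays with equal numbers after group means were removed ran from −0.0835 to 0.0846.

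Of the 300 list results, 230 were unchanged and 70 lost with the estimated correlation. With pseudocounts of 1, 64 and 1000, 299, 297 and 289 were unchanged, with quantile normalization 284 and with median scaling 273. Of 942 results for named genes, 938, 942 and 921 were unchanged with these pseudocounts, 916 with quantile normalization and 900 with median scaling. Leaving out cross-hybridising probe sets kept 759 of 810 and reversed 16. Dlk1 then changed by 0.87 log2 in IP14D-1 against MEF, −0.83 in IP14D-101 against CL11 and 0.54 in IP20D-3 against IP14D-101. In IP14D-101 against CL11, Acta2 became −2.05, Plagl1 −1.10, Ndufb8 −1.14, Ywhaz 0.13 and Plet1 0.25, and Lss against MEF became −0.11. Plagl1 became −0.051 in IP20D-3 against CL11, and in IP20D-3 against IP14D-1 Col3a1 became 0.0060, Acta2 0.073, Top2a −0.21 and Rps9 −0.37. Cenpa became 1.40 in IP20D-3 against IP14D-101. The remaining probe sets of Dlk1, Acta2, Plagl1 and Col3a1 lay below background in the groups compared. Ywhaz in IP14D-101 against IP14D-1 became 0.59, and 0.041 under median scaling.

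The axis position of IP14D-1 moved to 0.879 with the pseudocount of 1000, 0.852 with quantile normalization and 0.908 with dim genes left out. For IP14D-101 it moved to 0.939 with a pseudocount of 64, 0.967 with 1000, 0.924 with quantile normalization, 0.939 with median scaling and 0.983 with dim genes left out, and for IP20D-3 to 0.946 with 1000 and 0.965 with dim genes left out. The root mean square difference from CL11 became 0.430, 0.284 and 0.404 with the pseudocount of 1000 for IP14D-1, IP14D-101 and IP20D-3, and 0.509, 0.335 and 0.496 with dim genes left out. For IP20D-3 and IP14D-1 it became 0.276 and 0.322. The pseudocount of 1000 gave medians of −0.30, −0.26 and 0.04 for MEF-high genes and 0.17, 0.12 and −0.04 for ES-high genes in the order given for the block. Quantile normalization gave ES-high genes a median of 0.22 in IP14D-101 against IP14D-1 with a camera p of 0.0901. Genes changed against CL11 in all iPS lines numbered 712 with the pseudocount of 1000 and 107 at a 2-fold limit.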

Other observations

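Several lists differed the same way in IP14D-1 against CL11 and in IP20D-3 against IP14D-101, comparisons that share no arrays. Amino acid and ER stress genes rose (18 and 17 of 25; adjusted p = 0.0956 and 0.0937 with an estimated correlation) and hypoxia and glycolysis genes fell (17 and 13 of 27; adjusted p = 0.0863 and 0.182 with an estimated correlation), as did endoderm genes (15 and 16 of 25), the only calls to hold with that setting. Between IP20D-3 and IP14D-1 themselves these lists had adjusted p = 0.877, 0.0906 and 0.0906, endoderm passing under median scaling (adjusted p = 0.0458). Eif2s3y stood at 15.63 and 15.69 log2 in IP14D-1 and IP20D-3 and at 14.13 in CL11 and 14.19 in IP14D-101. Mid1 stood at 15.85 and 15.88 log2 against 12.26 in CL11 and 11.37 in IP14D-101. The mean actin 3' to 5' ratio was 1.37 and 1.28 against 1.21 and 1.22, with arrays of IP20D-3 and IP14D-101 overlapping, and the GAPDH ratio (0.850 and 0.795 against 0.809 and 0.795) did not divide the lines this way. Medium and array batch per line are not given, so they could not be compared with this division.

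Peg3, Usp29 and Grb10 were lower in IP14D-101 than in IP14D-1, Peg3 by 2.07 log2 and Grb10 by 2.33. IP14D-101 is the only line of the C57x129S2 background, so line and background could not be told apart.

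Between IP20D-3 and IP14D-1 Cap1 fell by 4.58 log2, Tmem87a was at least 6.84-fold lower and another probe set of Cap1 gave −4.03.

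IP14D-101 replicate 3 had the lowest correlation with its own group, 0.944.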
